A study of Mus musculus with 28 samples.

How the data were processed

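Chromatin immunoprecipitation with sequencing was done in IDG-SW3 cells, and 26 of the 28 samples had a list of called regions that was used here; the 2 input samples have no list used here. Per the submitters' processing notes, the tools named are Bowtie and HOMER and the build is mm9; versions, parameters, filters and the use of the inputs are not given in the sources used here. Each list was deposited per sample, so replicates were called separately. The deposited lists give chromosome, start, end and a score for each region. The score is the authors' own peak score, a number whose scaling is not stated. It was used to rank or filter regions within a list and to look for score steps. It also served to recount peaks above a common score and to compare deviations of site scores between replicates. Groups, days, doses and treatment times were taken from the sample labels, and the labels call the factor libraries biological replicates. Replicate 2 factor libraries and the histone libraries carry an index tag in their names that replicate 1 factor libraries lack, so the replicates may be 2 batches. Both arms hold 1 library of each, and per-replicate ratios are given for that reason.

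Chromosome names and lengths were checked against the NCBIM37 assembly, with 0 regions beyond a chromosome end, and genes came from the GENCODE M1 annotation of that build (22225 protein-coding genes). Coordinates are 1-based. Read depth is not stated. Distinct low scores (up to 60) of some lists fell on whole multiples of a step within 0.052, a tolerance chosen after seeing the data: for H3K4me2 the step was 0.839 at day 3 (100% of 58 scores) and 0.251 at day 35 (99.5% of 213), and for H3K4me3 0.898 and 0.557. A smaller step would mean a deeper library if lists were scaled alike, which is not stated.

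A consensus site was a peak of one replicate overlapping a peak of the other by at least 1 bp, the pair merged. A 1,25D3-only site overlapped no peak of either vehicle replicate. Peak numbers were compared by an exact two-sided permutation test of mean log2 peak number, 2 libraries against 2, which cannot give p under 0.333. Co-location with RXR and with marks was tested by 1000 circular shifts of the sites within chromosomes, one-sided, with Benjamini-Hochberg adjustment over 9 marks. For marks, each tail was adjusted separately and the tail of the observed direction is given. Such p values are smaller than those of a test that allows both directions. Shares of RXR sites were compared by Fisher's exact test. Sites were assigned to the nearest TSS of a protein-coding transcript and classed by their centre as within 1 kb of a TSS, coding exon, UTR, intron or intergenic. For gene lists, genes with a VDR site within 50 kb of the gene body were counted and compared with 10000 random lists matched in 10 bins of gene length, with adjustment over 14 lists. The background was all protein-coding genes. Histone coverage was the percent of the gene body with 5 kb on each side that called regions covered, and the median change of a list was placed among 10000 random lists matched in 10 length bins and 5 coverage bins. With 1 library per day, such percentiles describe these libraries and are not tests of the days.

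The gene lists (vitamin D targets, osteoblast, osteocyte, mineralization, Wnt, proliferation, interferon, adipocyte, chondrocyte, myogenic, haematopoietic and osteoclast, endothelial, neural and housekeeping), the tests and the alternatives were fixed before the data were examined, apart from the choices named here as made later. All 154 distinct listed genes were found, Spi1 by its older symbol Sfpi1. Genes were named by a fixed rule: the 20 genes nearest to the VDR sites with the best mean rank by score, listed genes with a VDR site within 50 kb, listed genes whose H3K27Ac coverage changed by over 10 points with H3K9Ac and H4K5Ac changing the same way, the 10 genes with the largest rise and the 10 with the largest fall by that condition, and Cyp24a1, Vdr, Tnfsf11, Sost, Dmp1, Phex, Mepe, Fgf23, Runx2 and Bglap in any case. The ranking of 1,25D3-only sites, the comparisons by vehicle call or RXR, the regions of chromosome 10, the Hox genes and the search for hormone response elements were chosen after the data had been seen. That search scanned 200 bp around each site centre and around points 2 kb to each side for 2 RGKTSA hexamers spaced by 3 bp, with at most 1 mismatch. The chromosome 10 block is the longest run of day-35 H3K4me3 regions at least 50 kb wide that lie within 500 kb of each other.

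Alternatives were an overlap of 50% of the shorter peak, peak centres within 500 bp, the higher-scoring 50% of each list, each replicate alone, a pairing of equal replicate numbers, lists limited to equal numbers, uniform placement in place of shifts, merging regions closer than 1 kb, autosomes alone, gene windows of 10 and 100 kb for VDR sites and of 20 kb or 2 kb around the TSS for coverage; leaving out the chromosome 10 block and using only sites not called in vehicle were added later. Peak numbers were also recounted above a common score, the highest of the lowest scores of the lists of a factor. The functions were tested on simulated data. Of 1000 simulated VDR sites the co-location count found all 300 placed on RXR regions, and 4 of 200 simulations of unrelated sites had p under 0.05. The consensus rule found all 500 simulated shared sites. The list test called 50 of 50 simulated lists of 20 genes with 8 at a site, and 5 of 200 random lists. Coverage matched a count base by base in 500 of 500 intervals. The element search, run without mismatches, found 200 of 200 planted elements. The setting with at most 1 mismatch, which gave the shares in the results, was not tested this way. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.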

Results

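IDG-SW3 is a mouse bone cell line that grows as osteoblasts at 33 °C with interferon gamma and matures into osteocyte-like cells at 37 °C, without interferon gamma, in mineralizing medium. It carries a transgene in which the Dmp1 promoter drives GFP, so reads from that promoter also count at Dmp1. Chromatin immunoprecipitation with sequencing gave 26 deposited lists of called regions. At day 35 the vitamin D receptor (VDR) and its partner the retinoid X receptor (RXR) were profiled after 3 h of vehicle or of 100 nM 1,25(OH)2D3 (here 1,25D3), the active vitamin D hormone, in 2 biological replicates per arm. At day 3 and day 35, 9 histone marks were profiled in untreated cells with 1 library each, so no day difference below has a replicate check. Factor lists held between 291 and 10333 peaks, each of one fixed width between 269 and 321 bp, and histone lists held between 9360 and 100123 regions. Read depth is not given in the sources used here, so the number of called regions sets the precision, and intervals on shares of sites are 95% Wilson intervals that cover counting error.

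More VDR sites and, by a smaller ratio, more RXR sites were called with the hormone than with vehicle. This comparison addresses where the receptor pair binds after a short exposure in osteocyte-like cells. VDR peaks numbered 1618 and 1333 with 1,25D3 (mean 1476 ± 202, SD, n = 2) and 291 and 342 with vehicle (317 ± 36.1, n = 2), a ratio of geometric means of 4.66, with 5.56 in replicate 1 and 3.90 in replicate 2. RXR peaks numbered 10333 and 7635 with 1,25D3 (8984 ± 1908, n = 2) and 6875 and 4093 with vehicle (5484 ± 1967, n = 2), a ratio of geometric means of 1.67, with 1.5 and 1.87 in the replicates. With 2 libraries against 2, the exact two-sided permutation test gave p = 0.333 for both factors, the smallest p this design allows. RXR lists reached lower scores with 1,25D3 (lowest 2.3 and 2.6) than with vehicle (3.3 and 3.6), and VDR lists did not (3.7 and 4.4 against 3.5 and 3.4). Depth and cut-off are not stated, so peak numbers cannot separate them from the hormone. Above a common score, more peaks were still called with 1,25D3 for both factors. The scores are not known to share a scale between lists, so this recount does not settle the matter. Both replicates called 1218 VDR sites with 1,25D3 and 283 with vehicle, and 6783 and 3628 RXR sites. Almost all vehicle sites were called again with hormone, 281 of 283 for VDR (99.3%) and 3434 of 3628 for RXR (94.7%).

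**Figure D1:**
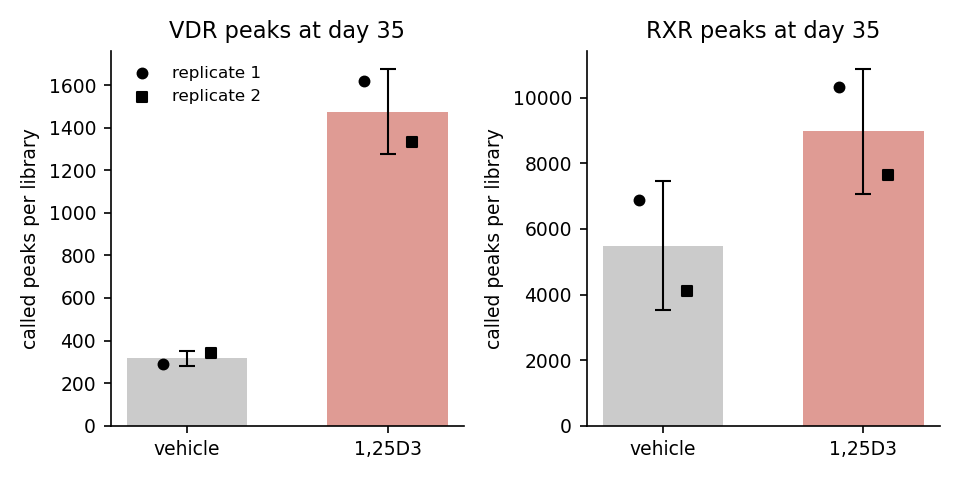
Called peaks per library for VDR and RXR at day 35 (y axis, number of peaks) with vehicle or 1,25D3. Bars are means of 2 replicates, error bars are the SD, circles are replicate 1 and squares replicate 2; VDR lists hold 1618 and 1333 peaks with 1,25D3 against 291 and 342 with vehicle.

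Of the 1218 VDR sites with 1,25D3, 893 (73.3%, 70.8 to 75.7) overlapped no peak of either vehicle replicate and are called 1,25D3-only here. These sites lay away from promoters. Only 9.41% (7.66 to 11.5) were within 1 kb of a transcription start site (TSS), 40.4% (37.3 to 43.7) were intronic and 48.5% (45.2 to 51.8) intergenic, with a median distance of 29.0 kb to the nearest TSS. The 325 sites that were also called in vehicle were nearly the reverse: 86.8% (82.7 to 90.0) were within 1 kb of a TSS, with a median distance of 0.064 kb. With the 1,25D3 lists limited to the length of the vehicle lists by score, the 1,25D3-only share was 36.7% of 278 sites, so the size of that share depends on where the lists end.

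The strongest VDR sites by the deposited score were promoters. The first site lay at the start of 2310044G17Rik (chromosome 12, 88288010 to 88288326, mm9), with scores of 334.2 and 278.1 in the replicates. It was followed by sites at Prpsap1, which regulates nucleotide precursor synthesis, Polq, a DNA repair polymerase, and Pcbp2, an RNA-binding protein. The 20 highest-ranked genes also held Arhgef1, Ift46, Ercc1, Trim41, Cct7, 9430023L20Rik, Rbm25, 2700007P21Rik, Tbpl1, Timm10, Cox7a2, Pfdn5, Sphk2, 2810422O20Rik, 1200014J11Rik and Mrpl12. All 20 sites were within 1 kb of a TSS and were called in vehicle too, 18 carried H3K4me3 at day 35, and 3 overlapped an RXR site (2310044G17Rik, Pcbp2 and Rbm25). Of all 276 sites called in vehicle that had no RXR site, 3.26% held the DNA element of the VDR and RXR pair, against 51.5% of 1,25D3-only sites.

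Among 1,25D3-only sites, ranked the same way after the data had been seen, all of the first 20 genes had RXR at the site, 12 sites were intronic, 6 intergenic and 2 near a TSS. The first was in an intron of Arid5b (chromosome 10, 67596620 to 67596936), a gene inside a stretch of chromosome 10 that was covered by most marks at day 35. Next came a site 25.0 kb from Dusp6, a phosphatase that acts on ERK, and sites within introns of Mical2 and Abcg8. Sparc, a major collagen-binding protein of bone, held an intronic site (chromosome 11, 55219368 to 55219684) with scores of 47.5 and 43.3. H3K27Ac covered 18 of these 20 sites at day 3 and 20 at day 35.

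Sites near known hormone targets were among those that appeared with 1,25D3. The promoter of Cyp24a1, the enzyme that degrades the hormone, held a site 0.238 kb upstream of the TSS (chromosome 2, 170322708 to 170323058) with RXR, and a further site lay 35.3 kb downstream of the TSS without RXR. Spp1, which encodes osteopontin, held a pair of sites with RXR, 0.747 kb (chromosome 5, 104863232 to 104863548) and 1.95 kb upstream (104862032 to 104862348). Mmp13, a collagenase, had a site with RXR 10.8 kb upstream (chromosome 9, 7261540 to 7261864), and Lrp5, a Wnt co-receptor, an intronic site with RXR 19.3 kb downstream of its TSS (chromosome 19, 3667119 to 3667446). Within 50 kb of their bodies, S100g and Trpv6, which carry calcium in gut and kidney, had 1 site with RXR each. Enpp3 had 2 sites, of which the stronger (chromosome 10, 24498134 to 24498450) was also called in vehicle. The site counted for Sp7, an osteoblast transcription factor, was the vehicle-called promoter site of Pfdn5.

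In all, 8 of the 23 listed vitamin D targets had a VDR site within 50 kb, against a mean of 2.77 in 10000 random lists of matched gene length (one-sided permutation p = 0.0042, adjusted p = 0.059 over 14 lists), which did not pass the threshold of 0.05. With the peaks of 1 replicate alone the count was 9 and 10, past it (permutation test, adjusted p = 0.015 and 0.007). In the same permutation test, 3 of 18 osteoblast genes (Sp7, Sparc and Spp1; adjusted p = 0.72) and 4 of 14 mineralization genes (Ank, Enpp3, Mgp and Spp1; 0.54) had a site. None of the 14 osteocyte markers had one, so Dmp1, Phex, Mepe, Sost, Fgf23 and Tnfsf11 (RANKL) held no site called in both replicates. Runx2, Bglap and Vdr itself had none either, although 3 replicate 1 peaks and 0 replicate 2 peaks lay near Vdr. The count was 2 of 17 Wnt genes (Lrp5 and Sfrp1), 3 of 16 proliferation genes (Myc, Aurka and Mcm2), 3 of 10 housekeeping genes (Actb, Rplp0 and Tbp), 2 of 9 chondrocyte genes (Sox5 and Sox9), 2 of 7 myogenic genes (Des and Myh3), 1 of 7 neural genes (Tubb3) and 0 of the 15 interferon, 8 adipocyte, 9 haematopoietic or osteoclast and 6 endothelial genes. The permutation tests of these lists had adjusted p values of 0.54 or more, and 2592 of all 22225 genes (11.7%) had a site. The sites counted for Des, Myh3, Mcm2, Tubb3, Rplp0 and Tbp were called in vehicle too. Those for Des, Myh3, Mcm2 and Tubb3 lay outside the listed gene, within 1 kb of the TSS of another gene. With 1,25D3-only sites the count was 0 for both myogenic and neural genes.

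**Figure D2:**
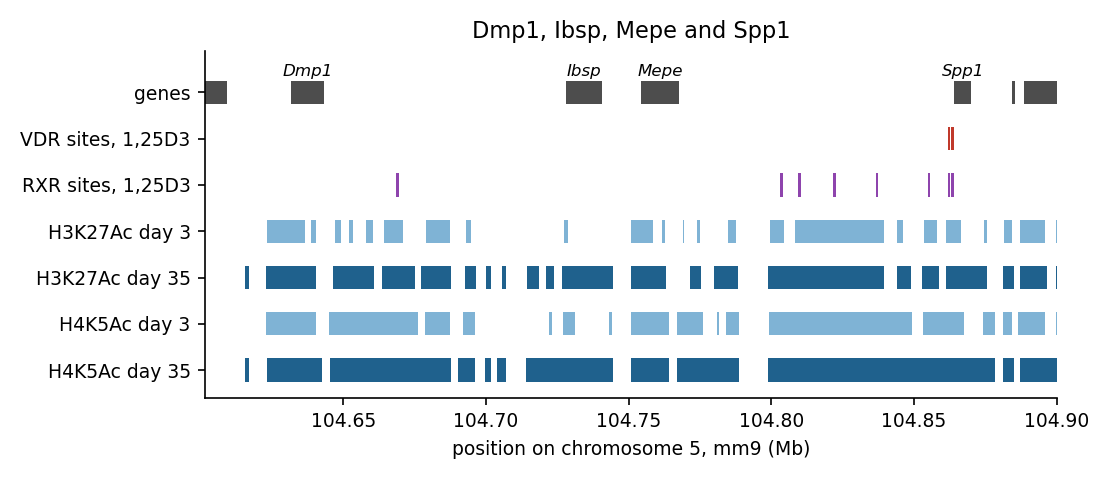
Map of the cluster of Dmp1, Ibsp, Mepe and Spp1 on chromosome 5 (x axis, position in Mb, mm9), with rows for genes, VDR and RXR sites called in both 1,25D3 replicates (drawn no narrower than a visible line), and regions of H3K27Ac and H4K5Ac at day 3 and day 35. The 2 VDR sites sit upstream of Spp1, while 8 RXR sites are spread over the interval, and H3K27Ac over Ibsp widens from 6.00% to 83.7% of the gene and its flanks.

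More of the VDR sites held RXR than after random shifts, although 515 had none. Of the 1218 VDR sites, 703 (57.7%, 54.9 to 60.5) overlapped an RXR site, against a mean of 0.196% after 1000 circular shifts of the sites along their chromosomes (one-sided permutation p = 0.001, the smallest these shifts can give). The shifts did not keep sites in regions with active histone marks. They therefore cannot tell pairing of the factors from a shared preference for such regions. The share was 73.2% (70.2 to 76.0) of 1,25D3-only sites and 15.1% (11.6 to 19.4) of those called in vehicle too, an odds ratio of 15.4 (Fisher's exact test, two-sided, p = 5.7e-77). RXR sites that appeared with hormone, 1303 of 6783 (19.2%; 50.9% without replicate 1 and 39.3% without replicate 2), held VDR at 26.2% (23.9 to 28.7), whereas RXR sites also called in vehicle held it at 6.59% (5.96 to 7.28). The odds ratio was 5.05 (Fisher's exact test, two-sided, p = 2.1e-79), and 1.82 without replicate 1 and 1.85 without replicate 2. Sites in 1 list are not independent, so these tests compare the lists and not the cultures. With the lists of a single replicate the share with VDR was 13.3% of 3885 and 13.7% of 4064 1,25D3-only RXR sites, against 7.73% and 7.88% of RXR sites also called in vehicle.

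Most day-35 VDR sites already carried active chromatin at day 3. H3K4me1, a mark of enhancers, covered 91.7% (90.0 to 93.1) of the sites at day 3 and 93.2% (91.6 to 94.5) at day 35, and H3K27Ac, a mark of active enhancers and promoters, 80.9% (78.6 to 83.0) and 87.4% (85.4 to 89.1). H4K5Ac covered 84.3% and 90.6%, H3K9Ac 68.5% and 69.3%, H3K4me2 64.8% and 75.7%, H4K20me1 38.8% and 27.4%, and H3K4me3, a promoter mark, 30.5% and 25.6%. Each of these 7 marks exceeded the shifted sites at both days (one-sided permutation p = 0.001, the smallest possible; adjusted p = 0.0013 over 9 marks). H3K36me3, a mark of transcribed gene bodies, covered 15.4% at day 3 (permutation test, adjusted p = 0.012) and 10.5% at day 35, below the shifted mean of 12.4% (adjusted p = 0.16). H3K9me3, a mark of silent chromatin, covered 2.30% at day 3 (permutation test, adjusted p = 1) and 1.23% at day 35, which was lower than the shifted mean of 2.84% (adjusted p = 0.009).

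The 2 kinds of VDR site differed in these marks. Sites also called in vehicle carried H3K4me3 in 89.8% of cases at day 3 and 80.9% at day 35, and 1,25D3-only sites in 8.85% and 5.49%. At 1,25D3-only sites H3K27Ac covered 74.7% (71.7 to 77.4) of sites at day 3 and 83.2% (80.6 to 85.5) at day 35, with 103 sites covered at day 35 alone and 27 at day 3 alone. RXR sites with 1,25D3 also lay mostly away from promoters, with 10.6% within 1 kb of a TSS and H3K4me3 at 7.84% at day 35. They carried H3K4me1 at 98.9% and H3K27Ac at 94.5% to 95.5% (interval; 6447 of 6783), a higher H3K27Ac share than at 1,25D3-only VDR sites. H3K36me3 and H3K9me3 lay below the shifted mean at RXR sites, at 10.5% and 0.280% (permutation test, adjusted p = 0.0045 each), and RXR sites under vehicle gave 9.95% and 0.221% (adjusted p = 0.0045 each).

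**Figure D3:**
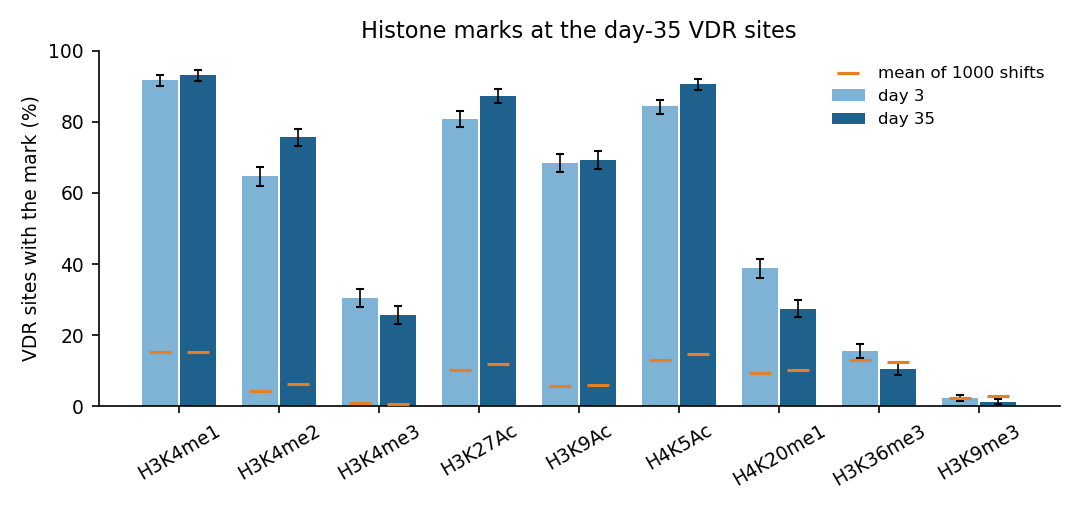
Percent of the 1218 VDR sites (y axis) that overlapped each histone mark (x axis) at day 3 and day 35. Bars are observed shares with 95% Wilson intervals and orange lines are means of 1000 shifts; H3K4me1, H3K27Ac and H4K5Ac cover 80.9% or more of the sites at both days, and H3K9me3 at most 2.30%.

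Across the genome H3K4me1, H3K9Ac and H3K36me3 covered similar lengths at both days, H3K4me2 covered more and H3K4me3 less at day 35, and the repressive mark H3K9me3 lay in different places; this comparison asks how chromatin differs between the osteoblast-like and osteocyte-like stages. H3K27Ac covered 225.8 Mb at day 3 and 270.1 Mb at day 35 (a ratio of 1.20), H4K5Ac 297.0 and 335.0 Mb, H3K9Ac 118.6 and 124.7 Mb, H4K20me1 215.9 and 245.3 Mb and H3K36me3 309.8 and 300.2 Mb. H3K4me1 covered 344.2 Mb at both days, in 91299 and 100123 regions. H3K4me2 went from 87.6 to 130.2 Mb and H3K4me3 from 17.61 to 12.97 Mb, with mean widths of 1922 and 1953 bp and of 1561 and 1385 bp. Without the chromosome 10 block, H3K4me3 covered 11.50 Mb at day 35 with a mean width of 1234 bp. Its ratio of day 35 to day 3 was then 0.655, against 0.736 with the block. Read depth is not stated, so these genome-wide lengths cannot separate depth from day for any mark.

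H3K9me3 covered 48.0 Mb at day 3 and 74.8 Mb at day 35, and only 17.1% of the bases covered at either day were covered at both, against 49.6% to 71.4% for the other 8 marks. The X chromosome carried most of the increase: its H3K9me3 went from 1.87 to 23.9 Mb (12.8-fold), while the autosomes went from 46.1 to 50.9 Mb (1.10-fold). Regions of H3K9me3 reached 23.7% of the 927 X-linked genes at day 3 and 58.9% at day 35, and 27.1% and 16.6% of 21281 autosomal genes. At day 3, 27.3% of autosomal H3K9me3 regions overlapped H3K36me3, and at day 35 2.78%. With 1 library per day, a property of either H3K9me3 library stays open beside a difference between the stages.

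**Figure D4:**
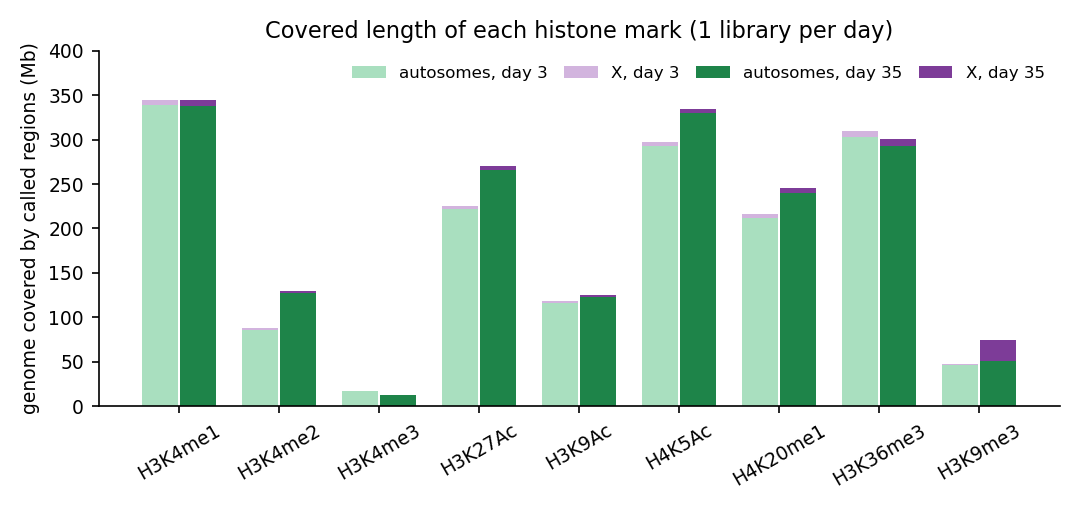
Length of genome covered by called regions (y axis, Mb) for each histone mark (x axis) at day 3 and day 35, 1 library each, split into autosomes and the X chromosome. H3K9me3 on the X goes from 1.87 to 23.9 Mb while its length on the autosomes goes from 46.1 to 50.9 Mb.

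Interferon response genes and cell cycle genes had less active chromatin at day 35 than at day 3. Of 15 interferon genes, 14 had lower coverage by H3K27Ac (by over 10 percentage points of the gene and 5 kb flanks), H3K9Ac and H4K5Ac, and none higher. Ciita, the master regulator of MHC class II, went from 50.1% to 3.67% covered by H3K27Ac, Psmb9, an immunoproteasome subunit, from 85.0% to 41.9%, and Gbp2 from 65.6% to 18.5%. The list's median change was -28.5 points for H3K27Ac, -36.3 for H4K5Ac, -23.0 for H3K36me3 and -15.4 for H4K20me1, each below all 10000 random lists of matched gene length and coverage. Of 16 proliferation genes, 8 were lower, among them Top2a (77.3% to 8.18%), Mki67 (28.9% to 5.29%) and Cdk1 (83.9% to 38.1%), and Ccnd1 was higher (68.9% to 89.0%). Their median changes of -13.8 points for H3K27Ac and -35.6 for H4K20me1 were also below all random lists. Growth and maturation of this line differ in interferon gamma and in temperature. The comparison of days cannot separate an effect of that switch from maturation for either list.

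Part of the osteoblast and mineralization genes had more, although both list medians for H3K27Ac lay within the middle 95% of random lists. Of 18 osteoblast genes, 9 were higher in all 3 acetyl marks and 1 was lower (Msx2, 22.4% to 3.88%). Ibsp, which encodes bone sialoprotein, went from 6.00% to 83.7% covered by H3K27Ac, Postn from 30.9% to 96.1%, and Pth1r, the parathyroid hormone receptor, from 47.5% to 100%. The main matrix genes Col1a1 (100% at both days), Col1a2 (97.4% and 99.3%) and Sparc (100% at both days), named after their values were seen, were near or at full coverage already at day 3. The list's median changes were 15.1 points for H3K27Ac (percentile 88.7 among random lists), 13.4 for H4K5Ac (99.4) and 6.84 for H3K9Ac (97.9). Of 14 mineralization genes, 8 were higher and none lower, with Phospho1 (32.2% to 95.1%), Smpd3 (16.8% to 77.8%), Ank (18.4% to 73.9%) and Alpl, the alkaline phosphatase (65.8% to 93.4%). Their medians were 14.8 points for H3K27Ac (96.6) and 21.1 for H3K36me3 (100). Of 17 Wnt genes, 7 were higher and none lower, with Lrp4 (25.1% to 94.8%) and Tcf7 (28.7% to 78.4%), at a median of 8.74 points for H3K27Ac (82.8) and 10.5 for H4K5Ac (99.2). Near start sites (2 kb each side), the osteoblast H4K5Ac and H3K9Ac, mineralization H3K36me3 and Wnt H4K5Ac medians were no longer outside the middle 95%.

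Among osteocyte markers, 5 of 14 were higher and none lower: Cd44 (52.5% to 96.4%), Gja1, a gap junction protein (an increase of 35.5 points), Capg (53.0% to 80.1%), Dmp1 (58.5% to 71.8%) and Tnfsf11 (6.14% to 19.2%). At Dmp1, where transgene reads also count, H3K4me3 covered 45.3% at day 3 and 45.6% at day 35, and H3K9me3 46.0% and 45.3%. Its coverage cannot be read as that of the endogenous gene alone. The osteocyte list's median change of 12.6 points for H3K27Ac had percentile 99.1, but near start sites (2 kb each side) it was 0, at percentile 77.5. Sost and Phex changed little (6.56% to 6.29% and 11.6% to 12.9%), Fgf23 went from 8.57% to 4.92%, and Mepe from 40.3% to 58.3% with H4K5Ac slightly lower. Runx2 was higher (64.9% to 84.7%), Bglap went from 19.1% to 29.4% with H3K9Ac lower, Vdr stayed at 12.9% and 12.7%, and Cyp24a1 had 0% on both days in untreated cells. Of 23 vitamin D targets 6 were higher and none lower, including Spp1 (37.2% to 88.0%), Mmp13 (21.3% to 53.6%) and Rxra (70.7% to 100%), at a median of 1.31 points (percentile 85.0).

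Lists for other cell types and for housekeeping genes lay within the middle 95% of random lists in H3K27Ac, as did the osteoblast, mineralization, Wnt and vitamin D lists. Median changes were 3.87 points for adipocyte genes (percentile 95.3; Fabp4 and Adipoq higher, Pparg lower), 0.755 for haematopoietic and osteoclast genes (81.5; Ctsk, Csf1r and Spi1 under its older symbol Sfpi1 higher), -1.59 for chondrocyte genes (4.13), -0.217 for endothelial genes (27.7), 0 for myogenic genes (51.3; Myf5 lower), 0 for neural genes (52.9) and 6.08 for housekeeping genes (47.6; Gapdh and Tbp higher). Over all 22225 protein-coding genes, 2556 were higher in the 3 acetyl marks by the same rule and 914 lower. The 10 with the largest increase were Capns2, Gm16721, Gm22, F2rl3, A130050O07Rik, Gm17544, Lifr, Ibsp, Gm9747 and Cdk5r1. The 10 with the largest decrease were the guanylate-binding genes Gbp7 and Gbp4, Ifnb1, which encodes interferon beta, Top2a, the histone genes Hist1h2ak, Hist1h2bn, Hist1h4k and Hist1h2bk, and the overlapping genes Gm15557 and Gdf5. Hist1h2ak, Hist1h2bn and Hist1h4k are neighbours whose windows with 5 kb flanks overlap, so their values are not separate. For short genes such as Gm17544, Gm16721 and Capns2 most of the window is flank.

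**Figure D5:**
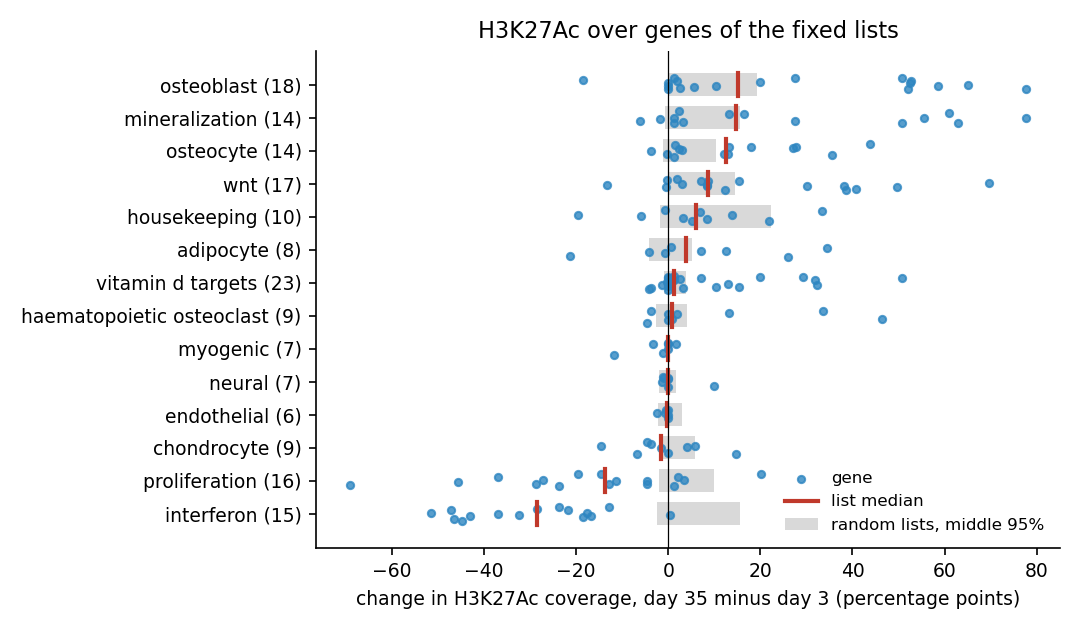
Change in H3K27Ac coverage of each gene (x axis, day 35 minus day 3, percentage points of the gene body and 5 kb flanks) for 14 gene lists (y axis, number of genes in parentheses). Points are genes, red lines are list medians and grey bars hold the middle 95% of medians of 10000 random lists; the interferon and proliferation medians, -28.5 and -13.8 points, lie below their grey bars and the osteocyte median, 12.6, above its bar.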

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

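All tests in this part were chosen after the result was seen. A signal appeared in the score column, which the day comparison does not use: 26 of the 90 highest-scoring regions of the 9 day-35 histone lists (10 per list) fell in 1.62 Mb of chromosome 10 (115789494 to 117409454), against 1 of 90 at day 3. This block holds 22 protein-coding genes, among them Mdm2, the negative regulator of p53, Frs2, Cct2, Cpm and Rap1b. H3K4me3, otherwise a narrow promoter mark, covered 2.94% of it at day 3 and 90.9% at day 35, H3K9Ac 15.4% and 68.6%, H4K5Ac 41.7% and 76.1%, and the silencing mark H3K9me3 15.8% and 48.3%. Greater depth at day 35 would widen regions in windows of the same size elsewhere. In H3K9me3 the block gained more than all 2948 of them (percentile 100). Those windows were not matched on coverage at day 3, so depth is not excluded. H3K4me3 served to choose the block, so its own gain there decides nothing. H3K9me3 also helped to flag it, with 5 of its 10 highest-scoring day-35 regions there. Activation of the block with differentiation would spare H3K9me3. Its percentile of 100 goes against activation alone, but is not independent of that flag. Extra DNA copies of the block in the day-35 cells may remain as an explanation, since marks of opposite kinds widened together; it cannot be told apart from others here, because H3K36me3 gained least, at percentile 89.9, and the input samples were not analysed here. The day-35 VDR and RXR lists held between 0 and 11 peaks in the block, at percentiles of 0 to 81.7, and peak numbers do not measure copies. The percentile is the share of windows with fewer peaks, so a list with 0 peaks in the block has percentile 0 in any case.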

How the results depend on the processing

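Of 737 values recomputed under alternatives for 203 results, 680 kept their side of the threshold or stayed within the margin set for them, 35 fell short of a threshold passed before, 15 newly passed one, 7 moved and 0 reversed; leaving out the chromosome 10 block and the sites called in vehicle were alternatives chosen after seeing the data. For covered length the margin was 1.5-fold, wider than most of the day ratios, so staying within it does not show that a day difference held. The H3K9me3 ratio of 1.56 was 1.10 without X, Y and unplaced sequence, and this was within the margin. Keeping the higher-scoring 50% of each list left 623 and 138 VDR sites and 3255 and 1682 RXR sites with 1,25D3 and vehicle, by construction. The 1,25D3-only share of VDR sites was 36.7% with lists of equal length and 75.8% to 82.1% without a replicate, where sites no longer had to be called in both replicates and numbered 1333 and 1618. With the higher-scoring 50% of the H3K36me3 regions, 10.0% of RXR sites carried the mark and the deficit missed the threshold (permutation test, adjusted p = 0.054; the cause was not tested). Vitamin D targets with a VDR site numbered 11 within 100 kb, 9 to 10 without a replicate and 7 with sites not called in vehicle (permutation test, adjusted p = 0.017, 0.015 and 0.007, and 0.0084), all past the threshold that 8 within 50 kb missed (0.059), and 4 within 10 kb (0.15). For H3K27Ac, the osteocyte median was 0 points near start sites and 6.12 with 20 kb flanks (percentiles 77.5 and 94.6), no longer outside the middle 95% of random lists, whereas with 20 kb flanks the mineralization median of 18.8 (99.99) and the chondrocyte median of -2.67 (0.69) were; the cause was not tested. Of the 35 and 15, 32 and 9 were list medians of the other 8 marks. Near start sites the osteoblast H4K5Ac and H3K9Ac, mineralization H3K36me3 and Wnt H4K5Ac medians were 0 and no longer outside the middle 95%, while the interferon and proliferation medians printed in the comparison of days stayed outside it under each alternative. The numbers of the replicates are not stated to pair libraries, and replicate deviations of site scores correlated across arms with r = 0.307 over 281 VDR sites and 0.182 over 3434 RXR sites. A fit with the replicate block gave log2 ratios of 2.22 (VDR) and 0.74 (RXR), equal by construction, so they say nothing about stability, and matching sites within replicate numbers gave a 1,25D3-only share of 73.3%. Unknown depth limits the day comparison of all marks and the comparison of peak numbers between arms. Merging regions closer than 1 kb moved nothing, since no regions lay that close.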

Other observations

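The tests of the hormone response element against flanks and against 1,25D3-only sites, of RXR peaks in single lists, and of the spread of the X-linked gain along the chromosome, were set before their results were seen; all others in this part were chosen after. The DR3 element, a pair of direct repeats spaced by 3 bp that the VDR and RXR pair is known to bind, separated the kinds of VDR site. It was found with at most 1 mismatch in 51.5% (48.2 to 54.8) of the 893 1,25D3-only sites, against 4.65% of flanking windows. Among these sites it was more frequent where no RXR site was called (61.5%, 55.2 to 67.4, of 239) than where one was (47.9%, 44.1 to 51.7, of 654), with an odds ratio of 1.74 (Fisher's exact test, two-sided, p = 0.00037). Of 49 sites called in vehicle that had RXR, 40.8% (28.2 to 54.8) held the element.

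On the autosomes H3K9me3 lay less often in active chromatin at day 35 than at day 3. At day 3, 27.3% of 31517 autosomal regions overlapped H3K36me3 and 25.6% H3K4me1, and at day 35 2.78% and 4.02% of 33952. Over 39 Hox genes, which pattern the body axis, the median share of the gene covered by H3K9me3 was 41.7% at day 3 and 0% at day 35, with 24 genes lower and 0 higher. Neighbouring Hox genes can share a region, so these genes are not independent counts. Among all autosomal genes, the share reached by an H3K9me3 region was 27.1% at day 3 and 16.6% at day 35. A second stretch of chromosome 10 (67457129 to 67937451), with Rtkn2 and Arid5b, had H3K4me3 over 3.86% at day 3 and 98.7% at day 35, H3K9me3 over 13.8% and 26.8%, and H3K36me3 over 53.8% and 41.3%. These are values of 1 library per day.

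The 276 VDR sites called in vehicle without RXR, such as those at the promoters of Prpsap1 and Polq, may not be bound through the element. It was found in 3.26% of them (1.72 to 6.08), close to the share of their flanks (3.80%, 21 of 552 windows). Hormone-independent binding through the element was argued against by a share -48.3 points from that of 1,25D3-only sites (-51.9 to -43.9). RXR below the authors' threshold cannot be told apart. An RXR peak in 1 of the 2 lists lay at 10.1% of these sites (7.11 to 14.3). That share was above 0.270% after shifts and below 40.2% of 1,25D3-only sites without RXR. The sites ranked high for VDR (medians at 16.5% and 21.4% of the replicate lists with 1,25D3). A call in the short vehicle lists may favour such ranks, which was not tested, so the ranks decide nothing. Whether open promoters were captured without VDR, or VDR was held there by other proteins, remains open, and a library without VDR was not analysed here.

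The gain of H3K9me3 on the X chromosome may be a change of chromatin with days in culture. More copies of an X with the same marks as at day 3 would raise its share of every mark. In the other 8 marks the median ratio of X shares was 1.10 (0.793 to 1.27), against 8.21 for H3K9me3. Copies of the X with H3K9me3 but few of the other marks would not be seen this way and stay open. A deeper day-35 library would raise the autosomes too, but their covered length was 1.10-fold that of day 3, against 12.8-fold for the X. The gain was spread along the chromosome, in 156 of 156 windows of 1 Mb (100%, at least 97.6) against 56.6% of autosomal windows. With 1 library per day, a property of that library stays open beside a change in the cells.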
